A study of Mus musculus with 12 samples.

How the data were processed

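Mouse bone marrow-derived macrophages were grown for 7 days with GM-CSF at 50 ng/mL. They were then left untreated, or received plasminogen (PLG) that had been exposed to EACA (6-aminohexanoic acid, a lysine analogue that binds plasminogen), or PLG that had been exposed to EACA and RNases, for 24 h. Each of the 3 groups had 4 libraries of total RNA, made with a directional kit per the labels' protocols. The labels do not say whether the 4 libraries of a group came from separate animals or separate cultures, so every p-value measures only the spread between these samples. No group received EACA without plasminogen or plasminogen without EACA, and the labels state neither an endotoxin content nor a vehicle for untreated cells, so a difference from untreated cells cannot be assigned to plasminogen alone. All 12 libraries were used, in the groups that their own labels give.

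The deposited values were FPKM, 1 column per library, for 32246 genes. The submitters' processing notes name cutadapt 4.5, FastQC 0.12.1, STAR 2.7.11a, featureCounts 2.0.6, DESeq2 1.40.2 and the genome build GRCm38.p6, with no role or order given. Per the labels and the table itself, the deposited FPKM had 3 decimals and no scaling between libraries: FPKM times the deposited gene length, taken in kilobases, summed to 1000000 in every library, within rounding. The deposited table also gave each gene's start, end and length, which are used here as GRCm38 coordinates counted from 1. Of the gene identifiers, 31595 matched GENCODE M21 with their version and had identical coordinates there, and 32156 matched without the version. Whether counting used the strand is not stated, so the values of genes that overlap another gene or lie antisense to one are uncertain, as are those of near-identical copies such as Hspa1a and Hspa1b. Symbols and biotypes were those of the deposited table.

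The depth of each library was recovered from the steps of the FPKM values, since FPKM times length of weakly expressed genes is a whole multiple of 1 read. The share of values within 0.1 of a whole number of reads was 100% in each library, and on simulated tables the recovered total was off by at most 0.00012%. Depth ran from 12940890 to 22677053 counted reads. Intervals and floors from reads would cover counting error only; the spread between libraries was larger, with a chi-square per degree of freedom of 3.21 to 35.0 over the 18 pairs of libraries within groups.

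Genes with an FPKM of at least 1 in at least 4 of the 12 libraries were tested, 11165 in all, on log2(FPKM + 0.5). The pseudocount shrinks the fold changes of genes with low values. Group means were fitted in 1 model for all 12 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend, not robust). The 3 comparisons were PLG+EACA against untreated, PLG+EACA+RNase against untreated, and PLG+EACA+RNase against PLG+EACA. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested within a comparison, with a threshold of 0.05. In counts of list members, the genes given as higher, lower, risen or fallen are those that passed this threshold. Single measures of a library were compared by exact permutation tests of 4 against 4 libraries, two-sided, for which the smallest possible p is 0.0286.

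The gene lists, the named-genes rule, the tests of genes and lists and the alternatives not marked as added were fixed before the data were examined. There were 32 lists: 20 of pathways and functions, 9 of cell type markers and 3 of RNA quality. Of their 642 symbols, 623 were in the table as written, 11 were matched by synonym and 8 were not in the table. A list with at least 5 tested members was tested with limma's camera at a preset correlation of 0.01 between genes, against all other genes tested, with Benjamini-Hochberg adjustment over the 27 lists of a comparison. Camera with an estimated correlation stands beside it. Fry, which does not set a list against other genes, is given where it did not pass for a list that camera called. The genes named for a comparison are the 10 with the largest positive and the 10 with the largest negative log2 fold change among those that passed the test, had a mean FPKM of at least 1, had groups that did not overlap and had a named symbol. For each list described, the rule adds the tested members with the smallest p, up to 4. Plg was given as a value. A few other members of the lists and other genes were chosen after their values were seen, and are marked as such. For 1 gene that the rule names, the result is not reported here.

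Both treatment groups were compared with the same untreated libraries, and PLG+EACA enters 2 of the 3 comparisons. Similarity and opposite change were therefore also computed with the shared libraries split into pairs, and on 20 simulated data sets with unchanged groups. In these data sets the noise was drawn independently for each gene. The limma steps were tested on simulated data drawn from the real means and depths. For PLG+EACA against untreated, 10500 simulated genes were left unchanged. Noise was independent between genes, and no library was shifted as a whole. In the real data 68.3% of the genes tested were called in that comparison. The simulated noise of a gene also had the same size in all groups. In the real data the chi-square per degree of freedom between libraries of a group was 3.21 to 6.16 in untreated cells. It was 5.89 to 35.0 with PLG+EACA and 7.93 to 24.3 with PLG+EACA+RNase. The simulated shares of recovered genes and of false calls may therefore not hold for the real calls of any of the 3 comparisons. For PLG+EACA against untreated, in 10721 simulated genes, 94% of genes raised by 1 on the log2 scale were recovered and 5.6% of calls were false. For PLG+EACA+RNase against untreated the values were 90% and 4.7% in 10734 genes, and for PLG+EACA+RNase against PLG+EACA they were 87.8% and 4.9% in 10748 genes. For genes raised by 0.5 the recovered share was 82%, 74.5% and 72% in the same order, and for genes lowered by 0.5 it was 74.5%, 74% and 75.5%.

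The alternatives were pseudocounts of 0.1 and 1, no filter and a stricter one (mean FPKM of at least 5), scaling by median-of-ratios, by TPM, by TPM without mitochondrial and ribosomal RNA genes and by quantiles, array weights, fits robust or without trend, a fit of the 8 libraries compared alone, the replicate number as a block, and each library left out in turn. Added after the values were seen were limma voom on the recovered reads, TPM of nuclear protein-coding genes, and a fit without replicate 4 of both treatments. Reads in silent genes were summed from the recovered reads and are given as RPM (reads per 1000000 counted reads), for protein-coding and long noncoding genes with a mean FPKM below 0.1 in untreated cells and below 1 over all libraries. Annotated genes that the table does not list under the same versioned identifier (23855) were taken as 0. These include genes that the table lists under another version (32156 identifiers matched without the version, 31595 with it). Intervals came from 10000 bootstrap resamples over genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.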

Results

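Total RNA was sequenced from mouse macrophages grown from bone marrow with GM-CSF, in 3 groups of 4 libraries. The groups were untreated cells, cells given plasminogen that had been exposed to EACA (PLG+EACA) and cells given plasminogen that had been exposed to EACA and RNases (PLG+EACA+RNase). The recovered depth of replicates 1 to 4 was 21734694, 14780530, 20465362 and 16796212 counted reads in untreated cells. It was 19506711, 22677053, 17862109 and 17518543 with PLG+EACA. With PLG+EACA+RNase it was 20389777, 16862058, 12940890 and 18949043. Across the 11165 genes tested, the first principal component held 55.9% of the variance and separated the untreated libraries (-37.1 to -43) from both treatments (12.3 to 29.3). The second held 15.5% and separated PLG+EACA (7.26 to 30.4) from PLG+EACA+RNase (-3.54 to -27.2), with replicate 4 the highest of each treatment. The noncoding RNA Gm26917, which lies over a copy of the ribosomal RNA gene, took 11% ± 0.73 of the counted reads in untreated cells, 12.4% ± 1.42 with PLG+EACA and 13.9% ± 0.923 with PLG+EACA+RNase (mean ± SD, n = 4). The transcript of plasminogen itself, Plg, was listed at an FPKM of 0 in untreated cells, 0.0103 ± 0.00695 with PLG+EACA and 0.02 ± 0.00876 with PLG+EACA+RNase, and was not tested.

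The comparison of PLG+EACA with untreated cells asks how macrophages given the plasminogen preparation without RNase exposure differ from cells left untreated, with no group given EACA alone. Interferon-stimulated genes (49 of 49) and cytokine genes (24 of 27) rose. Il27, which encodes a subunit of the cytokine IL-27, rose from an FPKM of 2.44 ± 0.516 to 80.3 ± 25.9 (mean ± SD, n = 4), a 26.9-fold change. The antiviral gene Oasl1 rose from 7.76 ± 1.59 to 210 ± 46.9, a 25.4-fold change, and Il12b, which encodes a subunit of IL-12, rose from 18.1 ± 3.07 to 320.1 ± 134. The largest decreases among named genes included the cannabinoid receptor gene Cnr2 (4.95-fold lower), Nfam1, a receptor with an immune signalling motif (57.3 ± 1.15 to 11.7 ± 1.4, 4.75-fold lower), and Cyp1a1, the best known target of the aryl hydrocarbon receptor (7.66 ± 0.353 to 1.28 ± 0.176, 4.6-fold lower). Other decreases were those of the sialic acid receptor gene Siglece (4.43-fold), Kcnj2 (3.91-fold), Cited4 (3.87-fold), Slc9a3r2 (3.87-fold) and Creg2 (3.79-fold), and of Mir5620 and Mir339, which lie within other expressed genes. Of the lists, cell cycle (24 of 28 genes lower) and cholesterol biosynthesis (17 of 23) ranked below other genes in camera, calls that ended with an estimated correlation (adjusted p = 0.606 with an estimated correlation for each). With median-of-ratios scaling 18 and 11 were lower and 3 and 1 higher.

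In limma with Benjamini-Hochberg adjustment, 1661 genes were higher and 5963 lower than in untreated cells, 68.3% of the genes tested, with 430 and 327 of them changed at least 2-fold. In 7218 genes all 4 values of one group lay above all 4 of the other, which chance gives in 2.9% of genes. The excess of lower genes followed the scale of the values: the median of all genes moved by -0.26 on the log2 scale, and after median-of-ratios scaling, which puts that median at -0.01, 3050 genes were higher and 2942 lower. Group medians are therefore given relative to all genes tested.

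All 49 tested interferon-stimulated genes rose, 49 also when adjusted over the list alone, with a median 2.66 above that of all genes on the log2 scale. The list ranked above other genes (limma camera, Benjamini-Hochberg adjusted p = 3.71e-39; adjusted p = 0.15 with an estimated correlation). Besides Oasl1, the largest changes were those of Rsad2, an antiviral radical-SAM enzyme (21.6 ± 5.05 to 477.3 ± 93.7, 21.8-fold), the nucleotide kinase gene Cmpk2 (19.6-fold), Ifit2, which binds viral RNA (17.6-fold), the chemokine gene Cxcl10 (10.3 ± 1.12 to 189.5 ± 88.2, 16.5-fold), Isg20 (14.4-fold) and Ifi205 (13.8-fold). Isg15, a ubiquitin-like modifier, rose from 43.5 ± 9.51 to 577.3 ± 88.3 (limma log2 fold change 3.73, SE 0.175, Benjamini-Hochberg adjusted p = 3.76e-08). Trim30c, a relative of Trim30a outside the lists, rose 20.7-fold. The interferon gene Ifnb1 itself, a member of the list chosen after its values were seen and given as a value only, rose from 0.499 to 3.29.

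Of 27 inflammatory cytokine and chemokine genes, 24 rose and none fell, 24 also when adjusted over the list alone, with a median 2.11 above all genes (limma camera, Benjamini-Hochberg adjusted p = 2.39e-21; adjusted p = 0.0702 with an estimated correlation). Cxcl2, a neutrophil chemoattractant, rose 6.1-fold (144.7 ± 17.4 to 882.7 ± 62.6), Cxcl1 8.51-fold and Ptgs2, the inducible cyclooxygenase, 9.71-fold (71.4 ± 4.62 to 702.5 ± 110). Of 24 NF-kB feedback and target genes, 18 rose and 3 fell, 18 and 3 also when adjusted over the list alone, with a median 0.56 above all genes (camera, adjusted p = 1.62e-09; adjusted p = 0.15 with an estimated correlation). Tnfaip3, an inhibitor of NF-kB, rose 2.4-fold and Nfkbia 1.88-fold. Nfkb2 rose 1.7-fold and overlaps another expressed gene, Psd. Of 14 inflammasome and IL-1 family genes, 11 rose and 1 fell, 11 and 2 when adjusted over the list alone, with a median 1.21 above all genes (camera, adjusted p = 1.18e-07; adjusted p = 0.178 with an estimated correlation), among them Nlrp3 (2.77-fold), Casp4 (1.95-fold) and Casp1 (1.64-fold).

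Of 16 class I antigen presentation genes, 15 rose, 15 also when adjusted over the list alone, with a median 0.79 above all genes (limma camera, Benjamini-Hochberg adjusted p = 4.54e-12; adjusted p = 0.0702 with an estimated correlation). The peptide transporter genes Tap1 and Tap2 rose 3.2-fold and 1.88-fold and H2-Q4 rose 2.13-fold, and each overlaps another expressed gene. Of 11 class II genes, 1 rose and 3 fell, 0 and 3 when adjusted over the list alone, and 5 rose and 1 fell with median-of-ratios scaling, which turns the balance (camera, adjusted p = 0.426). Of 13 costimulation and checkpoint genes, 6 rose and 3 fell, 6 and 3 also when adjusted over the list alone and 8 and 1 with median-of-ratios scaling, with a median 0.58 above all genes (camera, adjusted p = 0.00271; adjusted p = 0.334 with an estimated correlation). Cd40 rose 3.49-fold, Tnfsf4, the ligand of OX40, 3.01-fold and Cd274, which encodes PD-L1, 1.7-fold.

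The NRF2 and metal response list rose, with 15 of 19 genes higher and 1 lower, 15 and 1 also when adjusted over the list alone, and a median 0.9 above all genes (limma camera, Benjamini-Hochberg adjusted p = 5.48e-12; adjusted p = 0.0702 with an estimated correlation). The metallothionein gene Mt1 rose 3.58-fold (36.9 ± 3.24 to 133.2 ± 7.33), the zinc exporter gene Slc30a1 2.7-fold and the sulfiredoxin gene Srxn1 2.24-fold (181.9 ± 22.3 to 407.6 ± 32.6). Of 22 immediate early and growth factor response genes, 12 rose and 6 fell, 12 and 6 also when adjusted over the list alone and 14 and 3 with median-of-ratios scaling, with a median 0.56 above all genes. It was the 1 list of this comparison whose call held with an estimated correlation (camera, adjusted p = 4.51e-05; adjusted p = 0.0255 with an estimated correlation). Junb (1.76-fold, overlapping Prdx2), Dusp1 (1.54-fold, overlapping Ergic1) and Klf6 (1.52-fold) led it by p. Of 18 extracellular matrix and TGF-beta response genes, 8 rose and 5 fell, 8 and 5 also when adjusted over the list alone (camera, adjusted p = 0.0121; adjusted p = 0.15 with an estimated correlation; fry, adjusted p = 0.264), with Sdc4 2.32-fold higher and Itgb5 1.99-fold and Tgfbr1 1.58-fold lower. Of 15 alternative activation genes, 6 rose and 4 fell, 6 and 4 also when adjusted over the list alone (camera, adjusted p = 0.0164; adjusted p = 0.196 with an estimated correlation). Tgm2, which overlaps Rprd1b, rose 2.58-fold and the growth factor gene Pdgfc 1.78-fold, while Clec7a, the receptor dectin-1, was 1.46-fold lower. The calls of the last 2 lists ended with median-of-ratios scaling, and that of alternative activation also ended without PLG+EACA replicate 4 (adjusted p = 0.0661, and up to 0.411 over the alternatives).

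Of 28 cell cycle genes, 24 fell and none rose, 24 also when adjusted over the list alone, and 18 fell and 3 rose with median-of-ratios scaling (limma camera, Benjamini-Hochberg adjusted p = 0.011; adjusted p = 0.606 with an estimated correlation). The ribonucleotide reductase gene Rrm2 was 2.03-fold, Ccna2 2.02-fold and Mcm4 1.58-fold lower. Of 23 cholesterol biosynthesis genes, 17 fell and none rose, 17 also when adjusted over the list alone, and 11 fell and 1 rose with median-of-ratios scaling, with a median 0.19 below all genes, -0.19 on the log2 scale (camera, adjusted p = 0.0215; adjusted p = 0.606 with an estimated correlation). Acat2 was 2.24-fold, Sqle, which encodes squalene epoxidase, 1.96-fold and Lss 1.88-fold lower. This call ended without PLG+EACA replicate 1 (adjusted p = 0.0514).

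The other lists of this comparison did not rank apart from the rest of the genes in camera with the filter used and the values as deposited, with the balance of several turning with the scaling. Scores per library, relative to the median gene, were higher for the TLR, class II, plasminogen system, glycolysis, macrophage marker and ribosomal protein lists and lower for lipid-associated macrophage genes (exact permutation tests, n = 4, Benjamini-Hochberg adjusted p = 0.0406 each). The nucleic acid sensing and TLR list had 7 of 28 genes higher and 13 lower, 10 and 6 with median-of-ratios scaling (adjusted p = 0.557). The plasminogen system and proteolysis list had 7 of 24 higher and 10 lower, 10 and 5 with that scaling (adjusted p = 0.185). Cholesterol efflux and lipid handling had 4 of 22 higher and 13 lower (9 and 6; adjusted p = 0.857), lipid-associated macrophage genes 1 of 16 higher and 12 lower (3 and 6; adjusted p = 0.185), and lysosome and phagocytosis 4 of 27 higher and 18 lower (7 and 9; adjusted p = 0.519). Glycolysis and hypoxia had 7 of 25 higher and 12 lower (12 and 3; adjusted p = 0.163), and the unfolded protein and integrated stress response 5 of 22 higher and 10 lower (9 and 5; adjusted p = 0.519). In the lists for efflux and for the unfolded protein response, the signs of median, mean and test differed. Macrophage markers had 4 of 13 genes higher and 4 lower (6 and 4; adjusted p = 0.123), dendritic cell markers 2 of 12 higher and 6 lower (3 and 2 with median-of-ratios scaling; adjusted p = 0.785, signs differing), neutrophil markers 0 of 8 higher and 3 lower (adjusted p = 0.743) and stroma and endothelium markers 2 of 7 higher (adjusted p = 0.0801, signs differing, but 0.0478 without untreated replicate 4 and 0.0309 without PLG+EACA replicate 3). Among the RNA quality lists, 6 of 11 mitochondrial mRNAs were lower (1 with median-of-ratios scaling; adjusted p = 0.494, but 0.0288 with no filter), 7 of 11 nuclear and histone RNAs were lower (2 higher and 3 lower with median-of-ratios scaling; adjusted p = 0.557, but 0.0453 with no filter), and 4 of 25 ribosomal protein genes were lower, against 19 higher with that scaling (adjusted p = 0.393, but 0.00049 with that scaling). Mitochondrial mRNA took 0.671% ± 0.0444 of reads in untreated cells and 0.559% ± 0.0655 with PLG+EACA (exact permutation p = 0.0857, n = 4).

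**Figure D1:**
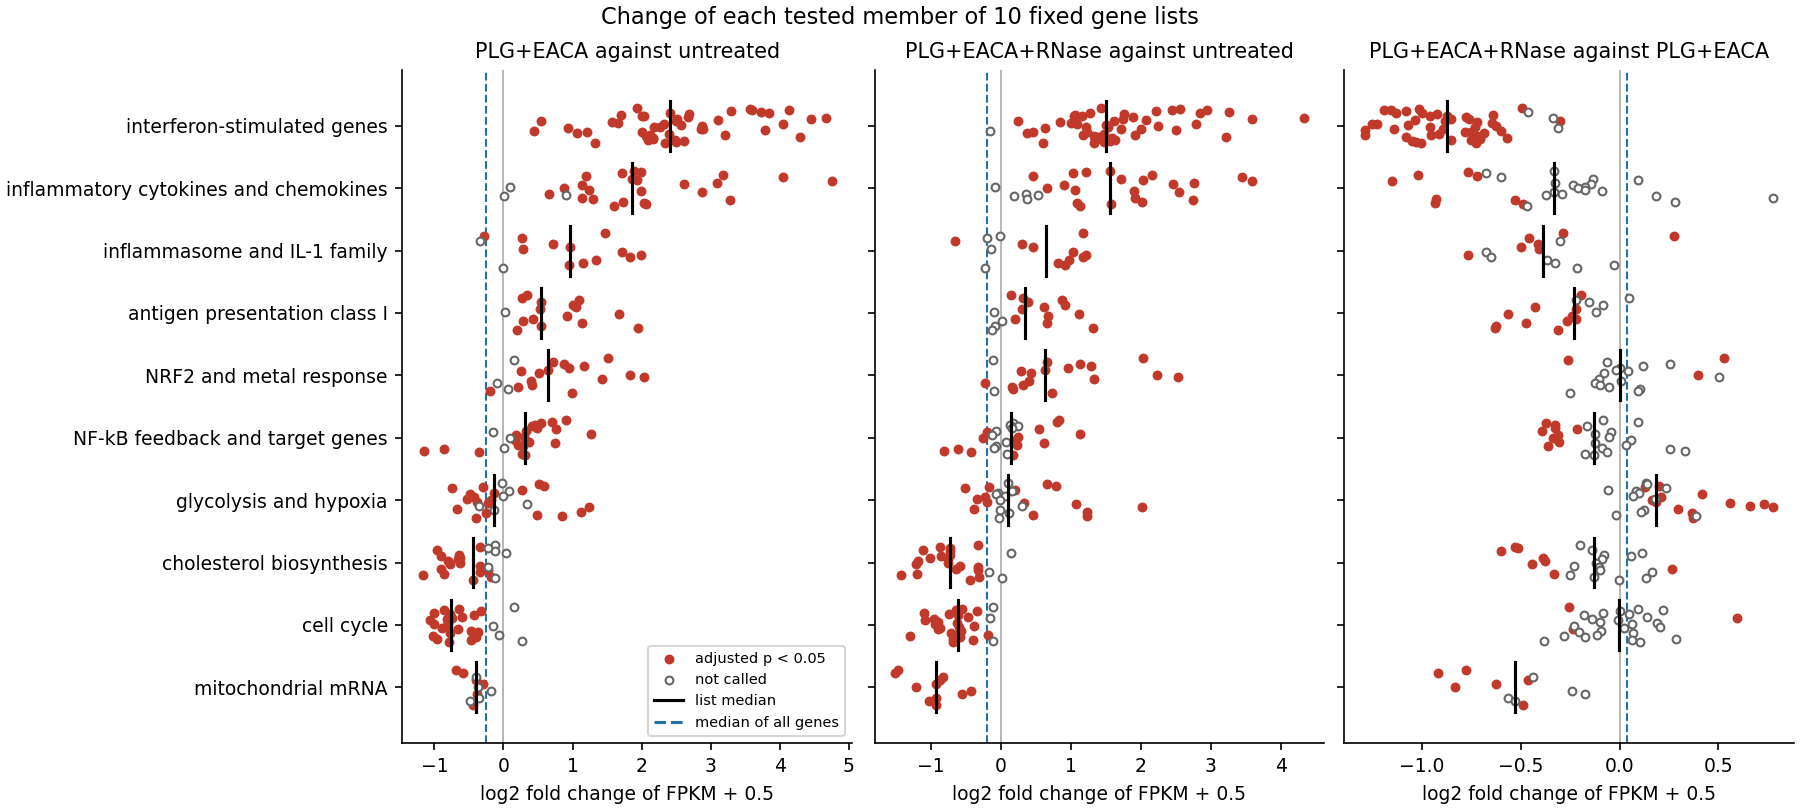
Log2 fold change (x axis, of FPKM + 0.5) of each tested member of 10 fixed gene lists in the 3 comparisons; filled points passed an adjusted p threshold of 0.05, black lines are list medians and the dashed line is the median of all genes. Interferon-stimulated genes lay above 0 in 49 of 49 cases with PLG+EACA against untreated. With PLG+EACA+RNase against PLG+EACA they lay below 0 in 49 of 49 cases, and 46 passed the threshold.

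The comparison of PLG+EACA+RNase with untreated cells asks how much of the response is left when the plasminogen preparation has been exposed to RNases. The interferon-stimulated genes (48 of 49) and cytokine genes (22 of 27) still stood above untreated cells. Oasl1 was 20.1-fold higher (7.76 ± 1.59 to 168.6 ± 50.4, mean ± SD, n = 4), Rsad2 12.1-fold, Il27 12.1-fold (to 37 ± 17.2), Il12b 10.9-fold (to 203.9 ± 47.7) and Isg15 9.62-fold. The largest increases, though, were in the paralogous genes of the inducible heat shock protein HSP70. Hspa1a rose 29.9-fold (0.335 ± 0.118 to 25.9 ± 9.59) and Hspa1b 24.9-fold (0.844 ± 0.0832 to 35.2 ± 13.3) (the value of each is uncertain, since the copies are near-identical). Cyp1a1 (5.49-fold), Nfam1 (4.86-fold), the potassium channel gene Kcnj2 (4.84-fold) and the transcription factor gene Cebpd (3.71-fold, overlapping Spidr) were lower. So were Slc9a3r2 (4.4-fold), Cnr2 (3.82-fold), Tifab (3.81-fold), the mitochondrial tRNA mt-Tn (6.07-fold) and the small RNA genes Mir7651 and Snord37, which lie within Zmiz2 and Eef2. Heatr9, which overlaps a small RNA gene, rose 11.3-fold.

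In limma with Benjamini-Hochberg adjustment, 1783 genes were higher and 5408 lower, 64.4% of those tested, with 473 and 243 changed at least 2-fold. In 6889 genes the groups did not overlap, against 2.9% by chance. The median of all genes moved by -0.2, and median-of-ratios scaling gave 3169 higher and 2953 lower.

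Of 49 interferon-stimulated genes, 48 rose, 48 also when adjusted over the list alone, with a median 1.71 above all genes (limma camera, Benjamini-Hochberg adjusted p = 1.33e-25; adjusted p = 0.394 with an estimated correlation). Cmpk2 rose 9.28-fold, and Trim30c, outside the list, 10.5-fold. Of 27 cytokine and chemokine genes, 22 rose, 22 also when adjusted over the list alone, with a median 1.76 above all genes (camera, adjusted p = 1.43e-16; adjusted p = 0.177 with an estimated correlation), including Cxcl1 (6.79-fold), Ptgs2 (6.72-fold) and Cxcl2 (5.53-fold). Of 24 NF-kB genes, 9 rose and 5 fell, 9 and 5 also when adjusted over the list alone, and 16 rose and 0 fell with median-of-ratios scaling (camera, adjusted p = 0.000359; adjusted p = 0.394 with an estimated correlation), with Tnfaip3 2.2-fold, Nfkbia 1.78-fold and Nfkbib, which overlaps Sirt2, 1.74-fold higher. Of 14 inflammasome and IL-1 family genes, 9 rose and 1 fell, 9 and 1 also when adjusted over the list alone (camera, adjusted p = 0.000549; adjusted p = 0.394 with an estimated correlation), with Nlrp3 2.27-fold and the IL-1 receptor antagonist gene Il1rn 1.96-fold higher. Il18bp, which encodes a decoy for IL-18 and overlaps Numa1, was 1.77-fold higher. Of 16 class I antigen presentation genes, 12 rose, 12 also when adjusted over the list alone (camera, adjusted p = 2.28e-06; adjusted p = 0.293 with an estimated correlation), with H2-Q4 1.83-fold, Tap2 1.59-fold and H2-D1 1.25-fold higher. Of 13 costimulation and checkpoint genes, 7 rose and 2 fell, 8 and 3 when adjusted over the list alone (camera, adjusted p = 0.00223; adjusted p = 0.394 with an estimated correlation), with Tnfsf4 2.52-fold and Cd274 1.54-fold higher and Icosl 1.56-fold lower.

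Of 19 NRF2 and metal response genes, 16 rose and 1 fell, 16 and 1 also when adjusted over the list alone, with a median 0.83 above all genes (limma camera, Benjamini-Hochberg adjusted p = 2.66e-10; adjusted p = 0.144 with an estimated correlation). Mt1 rose 4.7-fold, Slc30a1 2.51-fold and Srxn1 2.44-fold. Of 25 glycolysis and hypoxia genes, 9 rose and 6 fell, 9 and 6 also when adjusted over the list alone and 16 and 1 with median-of-ratios scaling (camera, adjusted p = 0.000715; adjusted p = 0.394 with an estimated correlation). Egln3, an oxygen-sensing hydroxylase, rose 4.06-fold (0.424 ± 0.181 to 3.27 ± 0.842), the peptide hormone gene Adm 2.36-fold and the hexokinase gene Hk2 1.73-fold. Of 22 immediate early and growth factor response genes, 11 rose and 5 fell, 11 and 5 also when adjusted over the list alone (camera, adjusted p = 0.000454; adjusted p = 0.0555 with an estimated correlation), with the phosphatase genes Dusp5 and Dusp1 2.06-fold and 2.02-fold and Junb 1.82-fold higher.

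Of 23 cholesterol biosynthesis genes, 20 fell, 20 also when adjusted over the list alone, with a median at -0.53 relative to all genes (limma camera, Benjamini-Hochberg adjusted p = 0.000612; adjusted p = 0.394 with an estimated correlation). Acat2 was 2.68-fold, the sterol carrier gene Stard4 2.28-fold and Sqle 2.16-fold lower. Of 28 cell cycle genes, 25 fell, 25 also when adjusted over the list alone (camera, adjusted p = 0.000715; adjusted p = 0.394 with an estimated correlation), with Rrm2 2.46-fold, Ccna2 2.14-fold and Mcm4 1.87-fold lower. All 11 mitochondrial mRNAs fell, 11 also when adjusted over the list alone and 9 with median-of-ratios scaling (camera, adjusted p = 0.00655; adjusted p = 0.538 with an estimated correlation). mt-Nd2, mt-Nd1 and mt-Nd5, which encode subunits of respiratory complex I, were 2.85-fold, 2.77-fold and 1.9-fold lower. The share of reads in mitochondrial mRNA was 0.436% ± 0.0353 against 0.671% ± 0.0444 (two-sided exact permutation p = 0.0286, n = 4). These changes stood beside a rise of Gm26917 from 11% to 13.9% of reads (exact permutation p = 0.0286).

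Camera called no other list in this comparison with the filter used and the values as deposited, though with no filter it called the TLR (adjusted p = 0.00249), cholesterol efflux (0.00652), lipid-associated macrophage (0.000694) and lysosome (7.86e-05) lists. Scores of some of these lists per library, relative to the median gene, did differ. Those of class II, alternative activation, the plasminogen system, extracellular matrix, dendritic cell markers and ribosomal protein genes were higher and that of cholesterol efflux lower (exact permutation tests, n = 4, Benjamini-Hochberg adjusted p = 0.0406 each). The nucleic acid sensing and TLR list had 6 of 28 genes higher and 18 lower (9 and 12 with median-of-ratios scaling; camera, adjusted p = 0.495) and class II antigen presentation 2 of 11 higher and 2 lower (6 and 0; adjusted p = 0.314). Alternative activation had 4 of 15 higher and 4 lower (7 and 3; adjusted p = 0.128), and the plasminogen system 8 of 24 higher and 9 lower (8 and 4; adjusted p = 0.356). Cholesterol efflux had 2 of 22 higher and 13 lower (9 and 9 with median-of-ratios scaling; adjusted p = 0.551). Lipid-associated macrophage genes had 1 of 16 higher and 12 lower (3 and 3; adjusted p = 0.258) and lysosome genes 2 of 27 higher and 18 lower (4 and 6; adjusted p = 0.258). The unfolded protein response list had 6 of 22 higher and 11 lower (9 and 6; adjusted p = 0.356), and the extracellular matrix list 8 of 18 higher and 6 lower (8 and 4; adjusted p = 0.0945). Macrophage markers had 1 of 13 higher and 4 lower (3 and 2; adjusted p = 0.93, signs differing), dendritic cell markers 2 of 12 higher and 4 lower (5 and 2; adjusted p = 0.356), neutrophil markers 1 of 8 higher and 3 lower (1 and 2; adjusted p = 0.684) and stroma markers 1 of 7 higher (2 and 0; adjusted p = 0.258, signs differing). Nuclear and histone RNAs had 1 of 11 higher and 6 lower (2 and 2; adjusted p = 0.684), and ribosomal protein genes 1 of 25 higher and 2 lower (17 and 0; adjusted p = 0.212, but 0.000602 with that scaling).

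**Figure D2:**
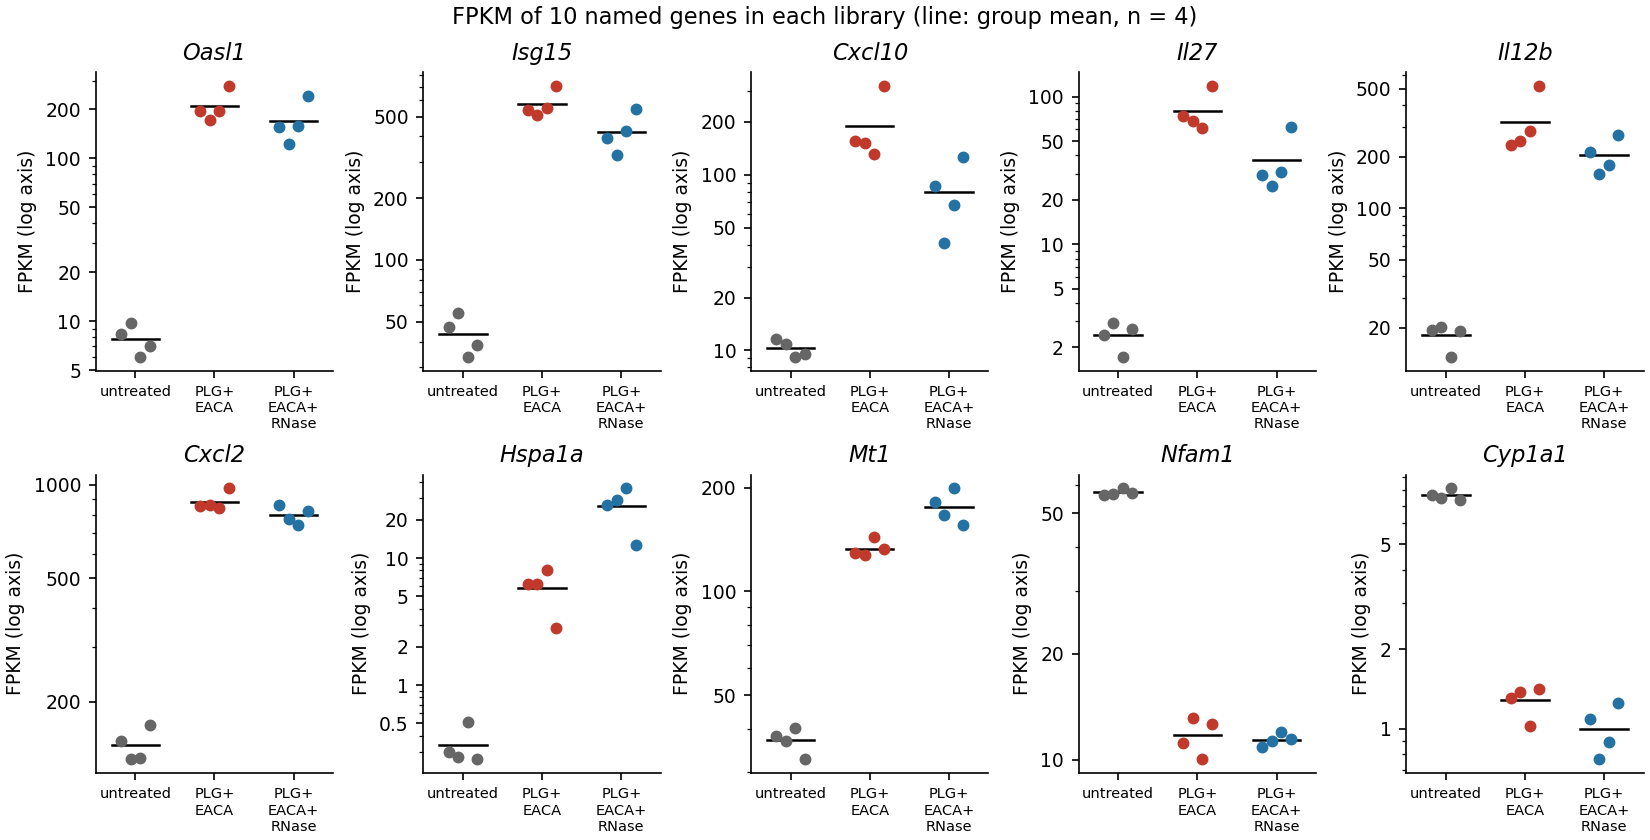
FPKM (log axis) of 10 genes in each of the 4 libraries of the 3 groups, with a line at each group mean. Oasl1, Isg15, Cxcl10, Il27, Il12b, Cxcl2, Hspa1a and Mt1 were higher and Nfam1 and Cyp1a1 lower in all 8 treated libraries than in the untreated ones, and Hspa1a averaged 25.9 with PLG+EACA+RNase against 5.87 with PLG+EACA.

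The comparison of PLG+EACA+RNase with PLG+EACA asks what exposure of the plasminogen preparation to RNases changed. All 49 interferon-stimulated genes had lower means on the log2 scale, and 46 of them passed the test. Cxcl10 averaged 80.2 ± 35.8 against 189.5 ± 88.2 (mean ± SD, n = 4, 2.38-fold lower), Ifit2 147.6 ± 70.7 against 323.3 ± 92.5 (2.29-fold lower) and Cd69, an early activation marker, 6.14 ± 2.69 against 16.5 ± 6.79 (2.57-fold lower). In the other direction, Hspa1a was 4.11-fold higher (25.9 ± 9.59 against 5.87 ± 2.21) and Hspa1b 4.04-fold higher (35.2 ± 13.3 against 8.12 ± 2.67). Glycolysis and hypoxia genes rose in 13 of 25 cases.

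In limma with Benjamini-Hochberg adjustment, 1349 genes were higher and 975 lower, 20.8% of those tested, with 80 and 44 changed at least 2-fold. The groups did not overlap in 2017 genes, against 2.9% by chance. The median of all genes lay at 0.04, and median-of-ratios scaling gave 1189 higher and 1269 lower. These counts rested on single libraries more than the others did. The 1349 became 514 without PLG+EACA+RNase replicate 2, 517 without replicate 3, 848 without replicate 1 and 769 without PLG+EACA replicate 4. The 975 became 433 and 412 without PLG+EACA+RNase replicates 2 and 3. The 80 genes became 42 and 48 without PLG+EACA+RNase replicates 2 and 3, and the 44 became 3, 11 and 88 without its replicates 2, 3 and 4 and 5 without PLG+EACA replicate 4. A fit of these 8 libraries alone gave 441 higher and 351 lower.

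Of 49 interferon-stimulated genes, 46 fell and none rose, 48 when adjusted over the list alone and 46 with median-of-ratios scaling, with a median at -0.91 relative to all genes (limma camera, Benjamini-Hochberg adjusted p = 1.1e-22; adjusted p = 0.388 with an estimated correlation). The list's score per library had a two-sided exact permutation p of 0.0286 (n = 4), 0.11 when adjusted over the lists. No smaller p is possible with 4 against 4 libraries. The same exact permutation p and adjusted p were those of the mitochondrial mRNA (difference -0.594), macrophage marker (-0.339), class I (-0.336) and TLR (-0.228) scores. They were also those of the cholesterol efflux score (-0.104) and of the glycolysis score, which rose (0.219). Ifi47, an interferon-inducible GTPase that overlaps other genes, was 2.2-fold lower, the guanylate-binding protein genes Gbp7 and Gbp2 1.61-fold and 1.52-fold lower, and Eif2ak2, the kinase PKR that binds double-stranded RNA, 1.65-fold lower. Genes outside that list with the largest decreases included Ms4a4c (2.49-fold), Calhm6 (2.43-fold), the cholesterol 25-hydroxylase gene Ch25h (2.24-fold) and Tnfsf10, which encodes TRAIL (2.23-fold). Cxcl9 was 2.34-fold lower (limma, Benjamini-Hochberg adjusted p = 0.0406), a call that ended without any 1 of untreated replicates 1 to 4, PLG+EACA replicates 2 to 4 or PLG+EACA+RNase replicates 2 and 3 (adjusted p of up to 0.117). Those of Cxcl10 and Ifit2 ended without PLG+EACA+RNase replicate 2 or 3 (up to 0.0619 and 0.0517), that of Ms4a4c without these or PLG+EACA replicate 4 (up to 0.071), and that of Ch25h without PLG+EACA replicate 4 or PLG+EACA+RNase replicate 3 (up to 0.0568). In a limma fit of the 8 libraries compared alone, the calls of Cxcl9, Cxcl10, Ms4a4c and Ch25h also ended (adjusted p = 0.0955, 0.0653, 0.0729 and 0.069). With no filter those of Cxcl9, Ms4a4c and Ch25h ended (adjusted p = 0.0856, 0.0565 and 0.0521).

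Of 27 cytokine and chemokine genes, 8 fell and none rose, 11 when adjusted over the list alone, with a median at -0.37 relative to all genes (limma camera, Benjamini-Hochberg adjusted p = 3.32e-05; adjusted p = 0.417 with an estimated correlation; fry, adjusted p = 0.0855). Il6 was 2.03-fold lower (82.6 ± 29.1 against 163.5 ± 41.7), Csf2, which encodes GM-CSF, 1.9-fold and Ptgs2 1.44-fold. Tnf, chosen after its values were seen, averaged 483.1 ± 37.4 against 611.1 ± 74.8 and did not pass (adjusted p = 0.0534). Of 24 NF-kB genes, 9 fell, 9 also when adjusted over the list alone (camera, adjusted p = 3.84e-05; adjusted p = 0.388 with an estimated correlation), with Icam1, Tnfaip2 and Bcl2a1d 1.24-fold, 1.24-fold and 1.28-fold lower. Of 14 inflammasome and IL-1 family genes, 6 fell and 1 rose, 9 and 1 when adjusted over the list alone (camera, adjusted p = 3.32e-05; adjusted p = 0.388 with an estimated correlation), with Casp4 1.41-fold, the DNA sensor gene Aim2 1.37-fold and Casp1 1.33-fold lower. Of 28 nucleic acid sensing and TLR genes, 8 fell and 2 rose, 10 and 3 when adjusted over the list alone (camera, adjusted p = 0.00463; adjusted p = 0.388 with an estimated correlation; fry, adjusted p = 0.0579), with Tlr2 1.68-fold, the DNA sensor gene Cgas 1.43-fold and Tlr4 1.25-fold lower. Of 16 class I genes, 11 fell, 12 when adjusted over the list alone (camera, adjusted p = 1.67e-06; adjusted p = 0.388 with an estimated correlation), with Psmb10 1.54-fold, Erap1 1.24-fold and H2-K1 1.14-fold lower, the last call ending with quantile normalization (adjusted p = 0.289).

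Of 25 glycolysis and hypoxia genes, 13 rose and none fell, 17 when adjusted over the list alone and 8 with median-of-ratios scaling (limma camera, Benjamini-Hochberg adjusted p = 4.95e-05; adjusted p = 0.388 with an estimated correlation). Egln3 rose 1.71-fold, the lactate exporter gene Slc16a3, which overlaps Csnk1d, 1.47-fold and Tpi1 1.33-fold, a call that ended without PLG+EACA+RNase replicate 2 (adjusted p = 0.0533). Of 23 cholesterol biosynthesis genes, 7 fell and 1 rose, 8 and 1 when adjusted over the list alone (camera, adjusted p = 0.000849; adjusted p = 0.388 with an estimated correlation; fry, adjusted p = 0.0579). Hmgcs1 was 1.44-fold and Msmo1 1.36-fold lower. The call of Hmgcs1 ended without PLG+EACA+RNase replicate 2 or 3 (adjusted p of up to 0.0517). Of 13 macrophage markers, 3 fell and 1 rose, 6 and 1 when adjusted over the list alone (camera, adjusted p = 0.00463; adjusted p = 0.388 with an estimated correlation). The phagocytic receptor gene Mertk (1.49-fold), the complement gene C1qb (1.49-fold) and Apoe (1.25-fold) were lower. These calls ended without PLG+EACA replicate 4 and without PLG+EACA+RNase replicate 3, among others (adjusted p of up to 0.0762, 0.0868 and 0.0944). That of Mertk also ended without PLG+EACA+RNase replicates 1 and 2, that of C1qb without PLG+EACA replicate 2 and PLG+EACA+RNase replicate 2, and that of Apoe without PLG+EACA replicates 1 and 2 and PLG+EACA+RNase replicate 1.

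Of 11 mitochondrial mRNAs, 6 fell, 10 when adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 1.12e-06; adjusted p = 0.388 with an estimated correlation), with mt-Nd2 1.89-fold, mt-Nd1 1.71-fold and mt-Nd5 1.54-fold lower. The tRNA mt-Ts2 was 3.07-fold lower, a call that ended without any 1 of PLG+EACA replicates 2 to 4 or PLG+EACA+RNase replicates 1 to 3 (adjusted p of up to 0.094). The share of reads in mitochondrial mRNA was 0.436% against 0.559% (two-sided exact permutation p = 0.0286, n = 4). Genes with any reads numbered 23820 ± 405 against 22094 ± 823 (exact permutation p = 0.0286). Of 540 long noncoding and unclassified transcripts tested, 126 were higher and 12 lower, 23.3% and 2.2%, against 12% and 9.6% of 9841 protein-coding genes (no test of this difference was made). Besides the HSP70 genes, the named genes with the largest increases were weakly expressed. They were Mir34a, which overlaps the transcript Gm37795 (3.38 ± 1.94 against 0.245 ± 0.287, 5.03-fold), Mir5623 within Atrnl1 (4.39-fold), the mast cell protease gene Prss34 (4.76-fold), Ankdd1a (3.17-fold, overlapping Spg21), Proz (2.78-fold) and Slc16a6 (2.63-fold, overlapping Arsg). Mutyh, a DNA glycosylase gene (2.9 ± 0.972 against 0.552 ± 0.221, 3.19-fold), and its neighbour Tesk2 (3.09-fold) were among them.

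Reads in genes that untreated macrophages do not express also differed. The 295 olfactory and vomeronasal receptor genes with a mean FPKM below 0.1 held 2.45 ± 0.299 RPM of the counted reads in untreated cells, 4.72 ± 0.925 with PLG+EACA and 15.5 ± 3.44 with PLG+EACA+RNase (mean ± SD, n = 4). Each difference between groups had a two-sided exact permutation p of 0.0286. Silent genes within 10 kb of an expressed gene held 68.8 RPM per Mb of exon with PLG+EACA+RNase, 31.1 with PLG+EACA and 23.5 in untreated cells. Silent genes more than 100 kb from any expressed gene held 8.6, 6.7 and 5.4. The silent genes near and far were chosen for low values in the untreated libraries, so their untreated values are low by selection.

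**Figure D3:**
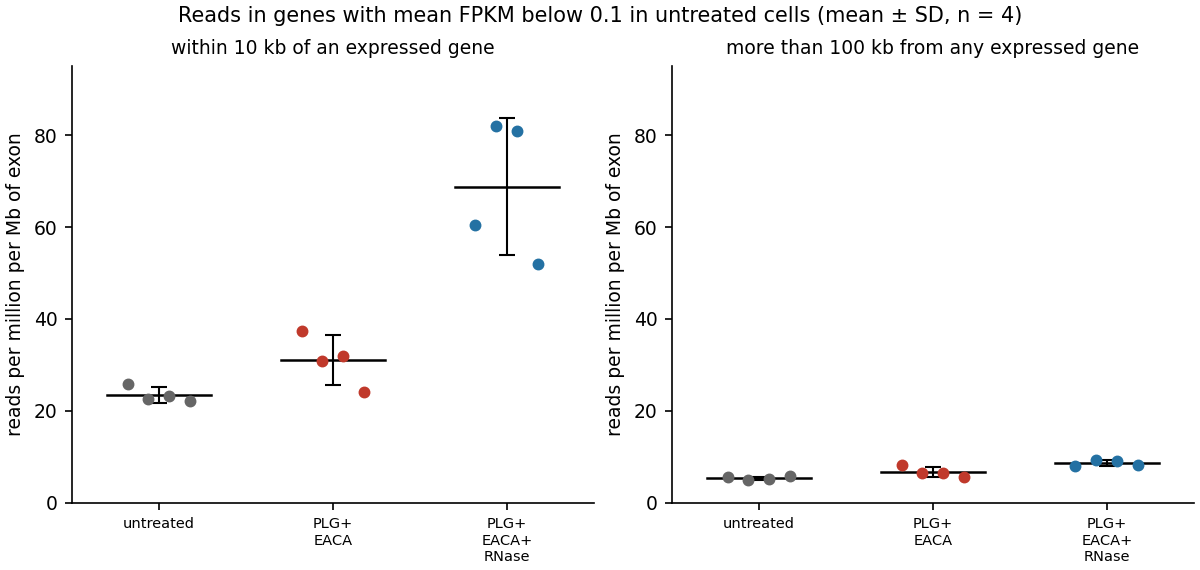
RPM per Mb of exon (y axis, from 0) in genes silent in untreated cells, for genes within 10 kb of an expressed gene and more than 100 kb from any; points are libraries, lines and bars are mean ± SD of 4. With PLG+EACA+RNase, the genes near expressed ones averaged 68.8 against 31.1 with PLG+EACA.

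Camera called none of the remaining lists in this comparison with the filter used and the values as deposited. With no filter it called alternative activation (adjusted p = 0.0187), the plasminogen system (0.0375), cholesterol efflux (0.00667), cell cycle (0.0203), extracellular matrix (0.0394) and stroma (0.0394), and with quantile normalization ribosomal protein genes (0.00623). Counts of genes higher and lower were 2 and 0 of 11 for class II antigen presentation (camera, adjusted p = 0.714), 0 and 1 of 13 for costimulation (0 and 3 with median-of-ratios scaling; adjusted p = 0.537), 0 and 0 of 15 for alternative activation (adjusted p = 0.216), 2 and 2 of 24 for the plasminogen system (adjusted p = 0.348) and 2 and 5 of 22 for cholesterol efflux (adjusted p = 0.162). They were 1 and 0 of 16 for lipid-associated macrophage genes (adjusted p = 0.537), 1 and 2 of 28 for the cell cycle (adjusted p = 0.301), 7 and 2 of 22 for the unfolded protein response (4 and 2 with median-of-ratios scaling; adjusted p = 0.389), 2 and 1 of 19 for NRF2 and metal response (adjusted p = 0.808) and 4 and 1 of 27 for lysosome genes (3 and 3 with median-of-ratios scaling; adjusted p = 0.531). They were 4 and 4 of 22 for immediate early genes (adjusted p = 0.724), 1 and 3 of 18 for extracellular matrix genes (adjusted p = 0.32), 2 and 0 of 12 for dendritic cell markers (adjusted p = 0.162, but 0.0137 without PLG+EACA replicate 3), 0 and 0 of 8 for neutrophil markers (adjusted p = 0.901), 0 and 1 of 7 for stroma (adjusted p = 0.255), 2 and 0 of 11 for nuclear and histone RNA (adjusted p = 0.537) and 1 and 0 of 25 for ribosomal protein genes (adjusted p = 0.642). The signs of median, mean and test differed for class II, costimulation, NRF2, immediate early, neutrophil and ribosomal protein genes.

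**Figure D4:**
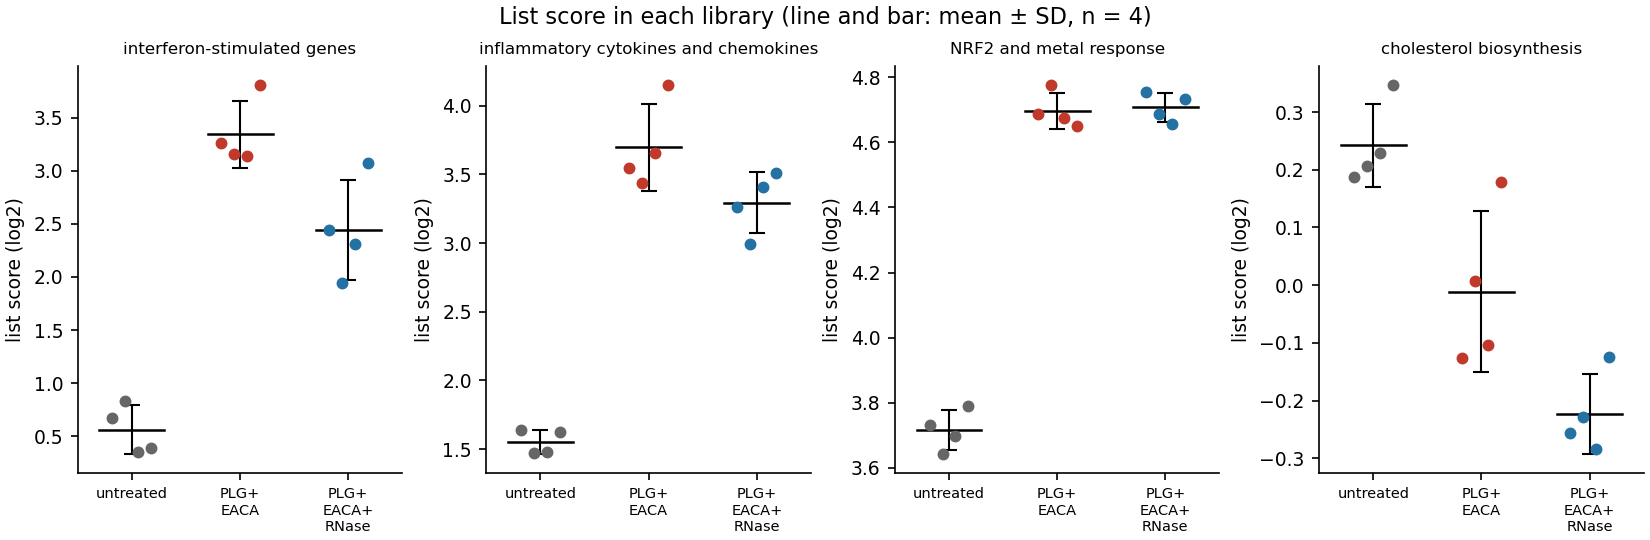
Score of 4 lists in each library (y axis, mean log2 value of the members relative to the library's median gene), with mean ± SD of the 4 libraries of a group. The interferon-stimulated score ran from 3.14 to 3.81 with PLG+EACA, 1.94 to 3.08 with PLG+EACA+RNase and 0.35 to 0.83 in untreated cells.

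Set against untreated cells, the 2 treatments changed largely the same genes. Of the 1661 genes higher with PLG+EACA, 1248 were also higher with PLG+EACA+RNase, where independent calls would share 265.3. Of the 5963 lower, 4834 were also lower, where independent calls would share 2888.3. The lower calls of both treatments partly follow the scale of the values, with medians of all genes at -0.256 and -0.203. Opposite calls numbered 10 and 21. Both sets of calls rest on the same untreated libraries. The log2 fold changes of both treatments correlated across genes at 0.854 with shared controls and at 0.795 when each treatment was set against a different pair of untreated libraries; genes are not independent replicates, so no p is given. Simulated unchanged groups gave 0.502 with shared controls and 0 ± 0.029 with split ones (SD over 20 simulations). The covariance was 0.264 with split controls, against 1e-05 in those simulations. In these libraries, genes called with PLG+EACA moved back toward untreated cells with RNase exposure more often than away. Of the genes called with PLG+EACA, 62.6% ± 1.9 (SD over 6 splits) changed in the opposite direction with RNase when different PLG+EACA libraries were used on each side, against 49.9% ± 1.3 in 20 simulated data sets with no change, where genes were taken at an unadjusted p below 0.05 rather than by an adjusted p. With these splits, an average of 1482 genes were higher with PLG+EACA. Of them, an average of 217.8 were called lower and 110.3 higher with RNase against the other PLG+EACA libraries. In the simulations the genes varied independently, while those of a real library can shift together, so the simulated SDs may be too narrow. The 6 splits reuse the same PLG+EACA libraries. Whether 62.6% lies beyond the spread between libraries was therefore not settled.

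Marker lists with fewer than 5 tested genes are given as sums of FPKM in untreated cells, with PLG+EACA and with PLG+EACA+RNase, and were not tested. Mast cell and basophil markers summed to 10.6, 14.4 and 17.1, eosinophil markers to 15.7, 18.3 and 16.7, B cell markers to 5.82, 2.89 and 4.21 and T and NK cell markers to 79.4, 85.5 and 80.4, nearly all of it Il7r. Erythroid and megakaryocyte markers summed to 460.9, 239.8 and 260.2, mostly from the platelet factor gene Pf4 and Car2. Neutrophil markers, tested above, summed to 435.5, 204.9 and 203.4, mostly from the collagenase gene Mmp8.

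For the genes that matter most, the locations on GRCm38 are as follows. Il27 (ENSMUSG00000044701.5) lies on chromosome 7 at 126589010 to 126594941, and Oasl1 (ENSMUSG00000041827.15) on chromosome 5 at 114923240 to 114937915. Cxcl10 (ENSMUSG00000034855.13) lies on chromosome 5 at 92346638 to 92348889, Isg15 (ENSMUSG00000035692.7) on chromosome 4 at 156199455 to 156200796 and Cd69 (ENSMUSG00000030156.5) on chromosome 6 at 129267325 to 129275436. Hspa1a (ENSMUSG00000091971.3) lies at 34969190 to 34972156 and Hspa1b (ENSMUSG00000090877.3) at 34956436 to 34959238, both on chromosome 17. Mutyh (ENSMUSG00000028687.17) lies at 116807723 to 116819440 and Tesk2 (ENSMUSG00000033985.17) at 116720948 to 116805956, both on chromosome 4.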

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

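Of the tests weighed in this part, the one on scaling and the one on RNase reaching the cells were written after the results they test were seen. All 49 interferon-stimulated genes were lower with PLG+EACA+RNase than with PLG+EACA (log2 fold changes of -1.291 to -0.301), and 46 of them passed the test. Were scaling between libraries the cause, other scalings would bring the list's median toward 0. Over 5 other scalings the list's median nearest to 0, not set against other genes, was -0.81, while the median of all genes ran from -0.005 to 0.06. Were it 1 outlying library, leaving that library out would do so, but without each of the 8 libraries in turn the median relative to all genes nearest to 0 was -0.74. RNase acting on the cells rather than on the plasminogen preparation cannot be told apart from loss of RNA in the preparation, since 0 groups received RNase without plasminogen.

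More reads fell in silent genes with PLG+EACA+RNase than with PLG+EACA: silent olfactory and vomeronasal receptor genes, which no comparison of single genes uses, held 15.46 RPM with RNase, 4.72 without, and 2.207 to 2.847 in the untreated libraries. Genomic DNA in the libraries would add reads evenly along the genome, but the reads gained per kilobase were 19.66 times as many in silent genes within 10 kb of an expressed gene as in those more than 100 kb away (95% bootstrap interval over genes 14.73 to 27.94). Read-through transcription past the ends of expressed genes is a candidate explanation, and it predicts larger gains in silent genes downstream on the same strand. These gained 2.14 times as many reads per kilobase as other silent genes within 10 kb (1.67 to 2.75). The ratio compares added reads, and the downstream genes already held more reads with PLG+EACA. The other silent genes within 10 kb also gained, by 28.8 RPM per Mb of exon against 61.6 downstream. Reads rose in 65.3% of them, against 72.5% of the downstream genes. Whether read-through also accounts for the gain in these other genes was not tested. No other biological explanation was tested, and unspliced or intronic RNA near expressed genes stays open, since the table holds no intron reads.

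More genes were lower than higher against untreated cells in the values as deposited. Genes that took a larger share of the reads could lower all others: leaving Gm26917 alone out of the totals moved the median log2 difference of PLG+EACA against untreated from -0.256 to -0.24. Leaving out Gm26917 and the genes at least 2-fold higher moved it to -0.158 (SE 0.023 over libraries), so these genes are not the whole cause. The reads of each library are shares of a fixed total, so a smaller share of some genes is balanced by a larger share of others. Of the 1661 genes called higher, only the 430 that were at least 2-fold higher were left out. The test therefore cannot tell how much of the remaining -0.158 the other higher genes account for. No biological explanation was tested.

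Several single values lay far from the other 3 of their group, by the gap to the nearest value divided by the range of the group, with the 95% limit for 4 samples as the bound. Chance gives about 1 in 20 such groups, and 22 of the 438 groups tested were past the limit. PLG+EACA replicate 4 accounted for many. It was high in Cd69 (0.855), Ms4a4c (0.959), Calhm6 (0.927), Ch25h (0.935), Ifi47 (0.922), Cxcl2 (0.835) and Hmgcs1 (0.845), and in Mir339, which was at 0 in the other 3 libraries (1.0). It was also high in the scores of the inflammasome and IL-1 family (0.881), lysosome and phagocytosis (0.852) and macrophage marker (0.917) lists. Stard4 was low in PLG+EACA replicate 1 (0.883).

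Among untreated libraries, replicate 3 was low in Il12b (0.888) and high in Hspa1a (0.846), Sdc4 (0.882) and the lipid-associated macrophage score (0.884). Replicate 4 was low in Siglece (0.888), replicate 2 was high in the class II antigen presentation score (0.851) and low in the plasminogen system score (0.97), and replicate 1 was low in the unfolded protein response score (0.846). In PLG+EACA+RNase replicate 2, Gm26917 took 15.24% of reads against 13.26% to 13.51% in the other 3 (0.877), and nuclear protein-coding genes took 82.66% against 84.32% to 84.49% (0.91).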

How the results depend on the processing

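The alternatives chosen after the values were seen were voom on recovered reads, TPM of nuclear protein-coding genes, both replicate 4 libraries of the treatments left out, counts at least 2-fold, and the unsplit values. No called gene list or named gene reversed its direction, while the balance of genes higher and lower in a comparison turned with median-of-ratios scaling. Where no cause follows from the construction of an alternative (fewer genes or samples, or a shift of all genes), the cause was not tested. All named genes of both comparisons with untreated cells kept their direction and call under each alternative that gave them a value. Some weakly expressed or mitochondrial genes had none, as with the stricter filter, and genes chosen after their values were seen were not repeated. For PLG+EACA+RNase against PLG+EACA, the call was lost in 22 repeats with other settings and kept in 750, and lost in 42 and kept in 546 with 1 library left out.

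Genes higher and lower with PLG+EACA against untreated (1661 and 5963) numbered 3050 and 2942 with median-of-ratios scaling and 3110 and 3059 with voom. Lower genes numbered 3194 with the stricter filter and 3722 with quantile normalization. With 1 library left out they ran from 1522 to 1693 and from 5398 to 6024. With PLG+EACA+RNase against untreated (1783 and 5408) they numbered 3169 and 2953 with median-of-ratios, 3194 and 3000 with voom. With the stricter filter they numbered 1058 and 3012, and 3306 were higher with no filter. The ranges with 1 library left out were 1613 to 1879 and 4786 to 5611. With PLG+EACA+RNase against PLG+EACA (1349 and 975), 773 were higher with the stricter filter, 636 lower with no filter, and 441 higher and 351 lower in a fit of the 8 libraries compared. With 1 library left out they ran from 514 (PLG+EACA+RNase replicate 2) to 1876 (replicate 4) and from 412 (replicate 3) to 1304 (replicate 4).

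At least 2-fold higher and lower with PLG+EACA against untreated (430 and 327), 277 and 126 genes passed with the stricter filter, and 763 were higher with voom. Lower genes numbered 578 and 196 with pseudocounts of 0.1 and 1, 125 with median-of-ratios, 556 with TPM, 565 with TPM without mitochondrial and ribosomal RNA genes and 155 with quantile normalization. With PLG+EACA+RNase against untreated (473 and 243) 216 and 98 passed with the stricter filter and 807 were higher with voom. Lower genes numbered 408 and 145 with those pseudocounts, 104 with median-of-ratios and 421 and 427 with the TPM scalings. With PLG+EACA+RNase against PLG+EACA (80 and 44), higher genes numbered 130 and 47 with pseudocounts of 0.1 and 1, 11 with the stricter filter and 129 with voom. Lower genes numbered 24 with no filter and 16 in the fit of 8 libraries. With 1 library left out they ran from 42 (PLG+EACA+RNase replicate 2) to 99 (PLG+EACA replicate 1) and from 3 (PLG+EACA+RNase replicate 2) to 88 (replicate 4).

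Of 81 list tests, 34 were called, 1 with an estimated correlation, 48 with no filter, 25 with the stricter filter, 36 with quantile normalization and 33 to 36 with 1 library left out. Calls gained with no filter included lipid-associated macrophage (adjusted p = 0.000397 and 0.000694) and lysosome genes (0.00327 and 7.86e-05) in both comparisons with untreated cells. Quantile normalization gained the first in both (0.00633 and 0.0362) and the second with PLG+EACA (0.0324). With the stricter filter, which drops members, calls ended for cell cycle (adjusted p = 0.715 and 0.291) and cholesterol biosynthesis (0.255 and 0.0547) in both comparisons with untreated cells, and for TLR (0.35), cholesterol biosynthesis (0.183) and macrophage marker (0.0979) genes between the treatments. They also ended for alternative activation (0.411) and extracellular matrix genes (0.079) with PLG+EACA against untreated. The share of PLG+EACA genes moving the opposite way with RNase (62.6%) was 60.56% with TPM, 59.97% with TPM without mitochondrial and ribosomal RNA genes and 65.18% unsplit. It was 57.83% (without PLG+EACA replicate 4) to 64.42% (without PLG+EACA+RNase replicate 4) with 1 library left out. The correlation of both treatments (0.795) was 0.7387 and 0.8157 with pseudocounts of 0.1 and 1, 0.6761 with no filter, 0.8753 with the stricter filter, 0.7533 and 0.7572 with the TPM scalings and 0.854 unsplit. It was 0.7586 (without untreated replicate 3) to 0.823 (without PLG+EACA+RNase replicate 2) with 1 library left out.

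With the replicate number as a replicate block, PLG+EACA against untreated gave 1691 higher and 6006 lower, PLG+EACA+RNase against untreated 1838 and 5446, PLG+EACA+RNase against PLG+EACA 1586 and 1092, 34 list calls, an opposite share of 63.1% and a correlation of 0.7534. Residuals of libraries with the same number correlated at -0.176 to 0.332, and 7 of 12 libraries correlated best with their own number, so the numbers may or may not pair cultures. Without replicate 4 of both treatments, PLG+EACA+RNase against PLG+EACA gave 1593 higher and 1295 lower.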

Other observations

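Every gene named in the first 2 paragraphs of this part, and the test of interferon against cytokine genes, were chosen after the values were seen. Several abundant transcripts changed alike with both treatments against untreated cells. Acod1, which makes itaconate, averaged an FPKM of 531.7 ± 27 in untreated cells, 1496 ± 182 with PLG+EACA and 1346 ± 155 with PLG+EACA+RNase (mean ± SD, n = 4; limma log2 fold changes 1.49 and 1.33, Benjamini-Hochberg adjusted p = 2.08e-07 and 4.6e-07). Inhba, which encodes the activin A subunit, rose from 232.1 ± 9.47 to 643 ± 98.8 and 537.4 ± 49.2, and the autophagy receptor gene Sqstm1 from 609.5 ± 35.5 to 1295 ± 203 and 1276 ± 91.2. The growth factor receptor genes Csf2rb (633.6 ± 12.3 to 382.3 ± 39.4 and 364.1 ± 18.7) and Csf1r (324.4 ± 7.02 to 186.5 ± 4.6 and 185.7 ± 6.42) fell with both. In the plasminogen system, Serpinb2, an inhibitor of plasminogen activators, rose from 158.3 ± 17.2 to 403 ± 118 and 247.5 ± 53.2. So did the urokinase receptor gene Plaur from 182.6 ± 9.8 to 249.2 ± 36.5 and 271.1 ± 27.1 and the collagenase gene Mmp13 from 64.2 ± 6.8 to 175.7 ± 22.2 and 143 ± 14.3. Mmp8 fell from 313.2 ± 39.6 to 119.4 ± 15.8 and 106.7 ± 10.

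A smaller set was highest with PLG+EACA+RNase. Gdf15, a stress-induced hormone gene, averaged 15.6 ± 1.23, 52.8 ± 20.7 and 113 ± 29.6 in the order untreated, PLG+EACA and PLG+EACA+RNase (limma log2 fold change between the treatments 1.14, Benjamini-Hochberg adjusted p = 0.0155). Hilpda, a hypoxia-inducible lipid droplet gene, averaged 6.63 ± 1.5, 11.7 ± 3.95 and 24.5 ± 6.15 (1.05, adjusted p = 0.0144), and Hmox1, which degrades haem, 450.1 ± 44.7, 1296 ± 236 and 1855 ± 245 (0.53, adjusted p = 0.0228). The transcription factor gene Klf2 averaged 2.33 ± 0.423, 2.4 ± 0.869 and 5.54 ± 1.37 (1.08, adjusted p = 0.00952). Of other heat shock genes, Hsp90aa1 (0.31, adjusted p = 0.0266), Hspa8 (0.24, adjusted p = 0.0137) and Hsph1 (0.58, adjusted p = 0.0203) rose between the treatments, while Dnajb1 (0.06, adjusted p = 0.443) and Bag3 (0.08, adjusted p = 0.275) did not pass. Among receptors for RNA, Tlr3 averaged 0.905 ± 0.175, 5.01 ± 2 and 2.2 ± 0.796 and Tlr7 20.3 ± 1.88, 22 ± 3.25 and 14.7 ± 2.23; both fell between the treatments (-1.02 and -0.56, adjusted p = 0.0155 and 0.0115).

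RNase exposure might act more on interferon-stimulated genes than on cytokine genes, as the medians of both lists between the treatments (-0.91 and -0.37 relative to all genes) would have it. The difference of both list scores per library averaged -0.851 ± 0.302 with PLG+EACA+RNase and -0.357 ± 0.11 with PLG+EACA (SD, n = 4), a difference of -0.494 with a two-sided exact permutation p of 0.0571. The lists share 0 members. The larger response of interferon-stimulated genes therefore cannot be told apart from the spread between these libraries, since the value of PLG+EACA replicate 3 lay below that of PLG+EACA+RNase replicate 4.

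Other splits of the 8 libraries compared into equal groups were fitted in the model of all 12 libraries. For PLG+EACA against untreated, 1 of the 35 splits of the 8 libraries, the real one, called as many as 7624 genes, and the highest other split called 1. For PLG+EACA+RNase against untreated the real split called 7191 and the highest other 0. For PLG+EACA+RNase against PLG+EACA the real split called 2324 and the highest other 962, a split that set PLG+EACA replicate 3 with the PLG+EACA+RNase libraries and PLG+EACA+RNase replicate 4 with the PLG+EACA libraries. A fit of these 8 libraries alone called only 441 genes higher and 351 lower for the real groups, and no other split was fitted that way. In each comparison the real split called the most genes. The other splits mix the 2 groups, so the difference between them enters the spread and few genes are called by construction. The splits therefore cannot exclude chance. The split with 962 calls also set replicate 4 of both treatments on the same side, and their residuals correlated at 0.332. Whether the calls come from PLG+EACA+RNase replicate 4 alone or from something that both libraries share was not tested.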
